A study of Drosophila melanogaster with 9 samples.

How the data were processed

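Messenger RNA was measured by stranded poly(A) sequencing in the fat body of Drosophila melanogaster, in 9 libraries made from 5 animals each. Eggs were kept at 21 °C for 21 h and animals were then raised at 25 °C. Per the submitters' processing notes, base calls were converted with bcl2fastq, reads were assigned to transcripts with Salmon 1.5.2, and DESeq2 was used downstream, with the genome build BDGP6. Each deposited file held 1 value per gene for 1 library, and no other column of values.

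The deposited values were a normalised signal, not the read counts that had been assumed before the data were examined. Over the 7791 genes above 0 in every library, each library had the same median ratio to the genes' geometric means, 0.9926, which is the mark of scaling by a median of ratios. The values were near whole multiples of a per-library unit for 69.8% to 76.8% of genes tested in this way (multiples up to 10, tolerance 0.05), so whole reads could not be recovered for every gene. That unit gave an estimated 18500000 to 29100000 reads per library, and 1 read was worth 0.746 to 1.38 of the deposited unit. The design fixed for such values was therefore used: limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(value + 1), on genes with a value of at least 1 in at least 3 libraries. The depth sets only the counting part of the error, and the spread between libraries was taken from the 3 replicates of each group.

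The files held 10242 gene identifiers. Symbols and positions were taken from an Ensembl gene annotation of BDGP6 for 10189 of them, and 53 had none. The filter left out 103 genes, and 10139 were tested. All 9 libraries entered a single fit with 1 coefficient per group, and each comparison was a contrast of 2 coefficients. P-values were adjusted by the Benjamini-Hochberg method over the tested genes, and a gene was called at an adjusted p under 0.05. All tests were two-sided. The labels do not say whether the replicates came from separate crosses or days, so the p-values may reflect technical spread more than the spread between populations of animals.

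Groups followed the sample titles, which give 3 larval libraries with a LacZ transgene, 3 prepupa libraries titled mitf and 3 titled LacZ. The other labels conflict with the titles. The genotype label gives the Mitf transgene to all 6 prepupa samples, and the column names inside the deposited tables give LacZ to the libraries titled mitf and mitf to those titled LacZ. The groups are called "titled mitf" and "titled LacZ" throughout, were not changed after the values were seen, and differences between them are given as titled LacZ minus titled mitf. The 2 stage comparisons set each prepupa group against the larvae.

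The gene lists, the tests and the rule for named genes were fixed before the data were examined. The lists cover the V-ATPase, lysosomal hydrolases and membrane proteins, autophagosome formation, autophagosome-lysosome fusion and late endosomes, TOR and FOXO signalling, the ecdysone response, larval serum and fat body proteins, antimicrobial peptides and humoral immunity, ribosomal proteins, the proteasome, oxidative phosphorylation, glycolysis and sugar storage, lipid storage and synthesis, heat shock and endoplasmic reticulum stress, and cell death and remodelling. Markers of hemocytes, salivary gland, muscle, gut, epidermis and imaginal discs, testis and gonad, neurons and ring gland, and genes of male dosage compensation and the Y chromosome, stood for other cell types. Each list was tested with camera in limma at a preset correlation of 0.01 on the same fit, adjusted over the lists, and again with the correlation estimated from the data. The effect of fry, which asks whether the genes of a list move on balance one way, is given under the dependence on processing. Of the Malpighian tubule, 20 markers were added after the data had been examined and before their own values were read.

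Named genes comprised 17 chosen in advance for autophagy, lysosomes, storage proteins and ecdysone signalling. They further comprised, in each comparison, the 6 largest rises and 6 largest falls among called genes whose groups did not overlap and whose higher group averaged at least 10 CPM, symbols that are only a CG or CR number left out. From each list in the first 8 above, up to 2 called members with the largest rise and 2 with the largest fall were taken, and from each other list 1 each way. Some genes were chosen for naming after their values were seen. They are members named only to spell out a count of 5 or fewer, Vha16-1, the tubule markers, and genes named in the closing section outside this rule.

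The procedure was tested on simulated data. The variance of each gene was kept up to a cap of 4 times the median variance, and changes were planted only above a minimum mean level. The rates may thus be too favourable for the noisiest and the weakest genes. They may also be too low for these comparisons. Changes were planted in few of the genes run on, whereas most tested genes were called in the data. The Benjamini-Hochberg cut is stricter when fewer genes change. At changes of 1.5, 2, 4 and 8 fold, each planted in 50 genes, the procedure recovered 26%, 50%, 94% and 98% between the prepupa groups. It recovered 16%, 60%, 84% and 92% between prepupae titled LacZ and larvae, and 22%, 46%, 82% and 96% between prepupae titled mitf and larvae. It made 6, 8 and 9 false calls, 4.29%, 5.97% and 6.82% of the calls, and gave no gene the wrong direction.

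Alternatives tried were scaling by library totals, scaling by a trimmed mean of log ratios (added after the data had been examined, trimming 30% of ratios and 5% of levels), no filter, a filter at 10 CPM in 3 libraries, pseudocounts of 0.1 and 5, a minimum log2 change of 1, the 6 compared libraries alone, a block for replicate number, removal of the 20 most abundant genes, and leaving out each library in turn. The alternatives that need whole counts were left out. Figures were drawn with matplotlib 3.10.9.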

Results

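Fat body RNA was sequenced from larvae titled e3IL, read here as early in larval instar 3, and from white prepupae. The white prepupa is the short stage at which the puparium forms. On that reading, the stage comparisons span the rest of the instar as well as the step to the prepupa, and can not separate them. The fat body is the insect organ that stores nutrients, secretes serum proteins and, at metamorphosis, breaks down its own cytoplasm by autophagy. All animals carried Lsp2-GAL4, which switches on a transgene in the late larval fat body. Whether it was already active in the larvae titled e3IL was not tested. The transgene was LacZ, a bacterial enzyme used as a control, or Mitf, the fly member of the MiT/TFE transcription factors, which are known to act on genes of lysosomes and autophagy. There were 3 libraries of larvae with LacZ, 3 of prepupae titled mitf and 3 of prepupae titled LacZ, each from 5 animals. The summed normalised read counts were 27178650, 25195639 and 22604438 in the larvae, 23922045, 23607147 and 24354238 in prepupae titled mitf, and 17896464, 17195757 and 18187221 in prepupae titled LacZ. Genes listed at 0 made up 11.5% to 15.1% of each larval library, 9.77% to 10.8% of each library titled mitf and 1.97% to 2.47% of each library titled LacZ. Across genes, log2 values of replicates correlated at 0.975 to 0.988 (Pearson), and those of different groups at 0.73 to 0.824. Levels below are means of normalised read counts ± SD over 3 libraries, and log2 differences are given ± SE from limma.

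Mitf (FBgn0263112, chromosome 4, 1198852 to 1224467, plus strand, BDGP6) was the check on the overexpression. Its transcripts stood at 378.2, 384.9 and 410.7 in the larvae and at 346.9, 370.4 and 407.1 in the prepupae titled mitf. They stood at 35204, 68535 and 45647 in the prepupae titled LacZ. The mean in prepupae titled LacZ was 132.9 times that in prepupae titled mitf, a log2 difference of 6.998 ± 0.201 (adjusted p = 1.72e-09), and the lowest library titled LacZ lay 85.7 times above the highest other library. Prepupae titled mitf and larvae did not differ detectably in Mitf (log2 difference -0.06 ± 0.20, adjusted p = 0.808). A table per gene does not separate transgene from endogenous transcripts. The labels conflict on which prepupa libraries carried the Mitf transgene, so every direction between the prepupa groups is given by title.

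**Figure D1:**
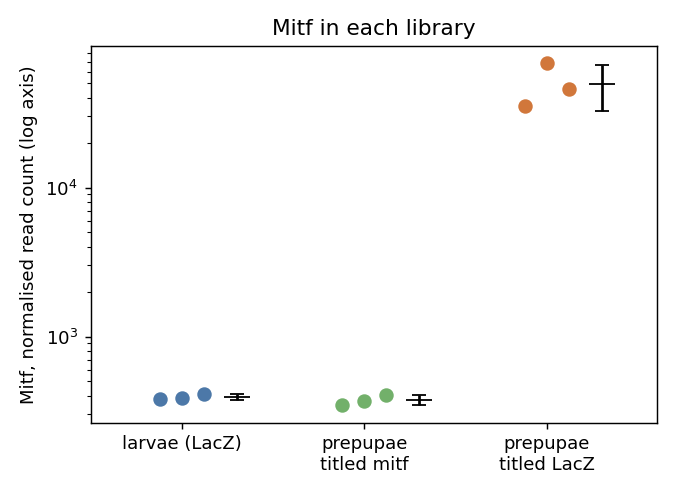
Normalised read count of Mitf (log axis) in each of the 9 libraries, with the mean and SD of each group of 3 to the right of its points. The 3 libraries titled LacZ lie between 35204 and 68535, and the other 6 between 346.9 and 410.7.

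The comparison of the prepupa groups addresses what Mitf overexpression does to the fat body at the white prepupa stage. Genes of the V-ATPase, the proton pump that acidifies lysosomes, were higher in prepupae titled LacZ for 21 of 23 measured subunits, with a median log2 difference of 3.91, or 3.69 above the median of all genes. The camera test called the list (adjusted p = 6.64e-07, and adjusted p = 0.534 with an estimated correlation). Vha100-2, a subunit of the membrane sector, averaged 18017 ± 3548 in prepupae titled LacZ and 242 ± 22 in prepupae titled mitf, a log2 difference of 6.20 ± 0.15. Vha36-3 was higher by 6.87 ± 0.53, and the most abundant subunit in these libraries, Vha16-1, by 3.91 ± 0.11. Vha100-4 averaged 168 ± 93.4 in prepupae titled LacZ and was listed at 0 in the prepupae titled mitf. Vha100-1 and VhaM9.7-c went the other way, at -1.29 ± 0.15 (-0.85 with library totals) and -2.29 ± 0.15. Markers of other tissues went both ways. Of 17 measured gut markers 10 were higher and 4 lower in prepupae titled LacZ (camera adjusted p = 0.601). Of 16 measured Malpighian tubule markers 10 were higher and 1 lower (median log2 difference 1.21). Testis and gonad markers were higher for 0 and lower for 5 of 7, and hemocyte markers for 2 and 3 of 10. Among all 10139 tested genes, 4166 were higher and 3200 lower.

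Proteasome subunits were lower in prepupae titled LacZ for 30 of 32 genes and higher for 0, with a median log2 difference of -1.87 (-2.09 from the median of all genes). The list was called at adjusted p = 6.44e-11, and at adjusted p = 0.695 with an estimated correlation. Rpn11, the deubiquitinase of the lid, averaged 626 ± 120 in prepupae titled LacZ and 4209 ± 223 in prepupae titled mitf (log2 difference -2.77 ± 0.13). The 2 subunits that were not called were Rpn1 (-0.43 ± 0.23) and Prosalpha1.

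Larval serum and fat body proteins were lower in prepupae titled LacZ for 9 of 11 genes, with a median log2 difference of -2.44 (-2.65 from the median of all genes). The list was called at adjusted p = 0.000752, and at adjusted p = 0.695 with an estimated correlation. Fbp1, the receptor through which the fat body takes up storage proteins, averaged 795010 ± 104500 in prepupae titled LacZ and 6366600 ± 88200 in prepupae titled mitf (log2 difference -3.01 ± 0.61). The storage protein Lsp2 differed by -3.84 ± 0.38, Lsp1alpha by -2.36 ± 0.29 and the iron carrier Tsf1 by -8.43 ± 0.15. The 6 storage and fat body proteins Lsp1alpha, Lsp1beta, Lsp1gamma, Lsp2, Fbp1 and Fbp2 together took 37.0% ± 7.12 of the larval libraries, 42.1% ± 0.714 of those titled mitf and 7.38% ± 0.989 of those titled LacZ. Fbp1 alone took 26.6% ± 0.486 of the libraries titled mitf and 4.47% ± 0.517 of those titled LacZ.

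**Figure D2:**
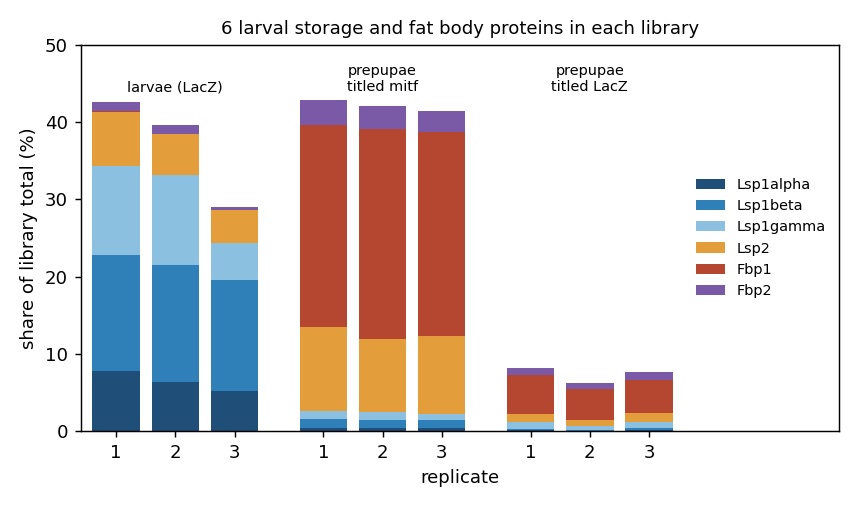
Share of each library's total (percent) taken by 6 larval storage and fat body proteins, as stacked bars for the 3 replicates of each group. Lsp1beta led in the larvae, Fbp1 made up 26.2% to 27.1% of the libraries titled mitf, and the 6 together stayed under 8.16% in each library titled LacZ.

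Autophagy genes split between the prepupa groups. Of 25 measured genes of autophagosome formation 10 were higher and 9 lower in prepupae titled LacZ. Atg14, a subunit of the lipid kinase complex that starts autophagosomes, differed by 4.07 ± 0.14 and Tango5 by 2.27 ± 0.11. The lipidation enzyme Atg3 differed by -4.19 ± 0.13 and the autophagy inhibitor Rubicon by -3.89 ± 0.13. ref(2)P, the adaptor that carries ubiquitinated cargo into autophagosomes, averaged 2568 ± 1565 in prepupae titled LacZ and 9261 ± 2007 in prepupae titled mitf (log2 difference -2.12 ± 0.50, adjusted p = 0.00322, and -1.40 without replicate 2 titled LacZ, at 773 the lowest of its group). The kinase Atg1 did not differ detectably (0.13 ± 0.24, adjusted p = 0.626), except without replicate 2 titled LacZ, where it was called at 0.45, and with library totals, where it was called at 0.57. The list was not called (adjusted p = 0.683), and its median (0.11), mean (-0.16) and test (lower) differed in sign. Library totals gave 14 higher, 7 lower and a median of 0.537, and trimmed mean scaling 7 higher, 10 lower and a median of -0.0388. Of 35 genes of fusion and late endosomes 13 were higher and 16 lower (adjusted p = 0.653), including dor (3.26 ± 0.11) and Plekhm1 (-2.23 ± 0.14). Their median was -0.18, their mean 0.08, and with library totals 15 were higher, 9 lower and the median 0.255, against 12, 17 and -0.32 with trimmed mean scaling.

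The calls of 4 further autophagy and hormone genes depended on single libraries. Atg8a, the ubiquitin-like protein that coats autophagosomes, was higher in prepupae titled LacZ by 0.56 ± 0.22. The call was lost without larval replicate 2, replicate 1 or 2 titled mitf, or replicate 1 or 3 titled LacZ (0.40 to 0.56), and with trimmed mean scaling (0.42). Thor, the translation inhibitor 4E-BP, was higher by 0.54 ± 0.19, which was lost without replicate 1 or 3 titled mitf, or 1 or 3 titled LacZ (0.34 to 0.54), and with trimmed mean scaling (0.40). The fusion SNARE Syx17 differed by -0.80 ± 0.29, which was lost without any 1 replicate titled mitf or replicate 2 titled LacZ (-0.81 to -0.44), and with library totals (-0.37). The ecdysone target br differed by -0.47 ± 0.16, which was lost without any 1 replicate titled mitf or replicate 1 or 3 titled LacZ (-0.48 to -0.39), and with library totals (-0.03).

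Lysosomal genes also went both ways, with 11 of 37 higher and 19 lower in prepupae titled LacZ. The list was not called (adjusted p = 0.138, and adjusted p = 0.695 with an estimated correlation), except as lower with library totals (adjusted p = 0.0458). The protease CtsL1 averaged 239490 ± 11500 in prepupae titled LacZ and 37108 ± 2871 in prepupae titled mitf (log2 difference 2.69 ± 0.18), and the lysosomal sugar carrier spin was higher by 5.25 ± 0.18. Cln3, the fly homologue of a gene for a lysosomal storage disease, averaged 1480 ± 77.5 in prepupae titled LacZ and 0.434 ± 0.752 in prepupae titled mitf. The protease cathD differed by -2.98 ± 0.22, the mannosidase LManI by -5.79 ± 0.38 and the membrane protein Lamp1 by -0.89 ± 0.10 (-0.45 with library totals). Among TOR and FOXO genes 10 of 28 were higher and 13 lower (adjusted p = 0.528, median -0.18, or 13 and 10 with a median of 0.247 with library totals), with rictor at 3.29 ± 0.19 and Sesn at -2.28 ± 0.12. Among ecdysone response genes 8 of 25 were higher and 9 lower (adjusted p = 0.771). The receptor EcR averaged 3018 ± 450 in prepupae titled LacZ and 147 ± 28.6 in prepupae titled mitf (4.35 ± 0.22), and Cyp18a1, which inactivates ecdysone, differed by 6.89 ± 0.41. Eip93F differed by -3.54 ± 0.49. The median of that list was 0.03, its mean 0.65 and its test lower, and the median was -0.0976 with trimmed mean scaling, while library totals gave 8 higher and 6 lower.

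Of 29 antimicrobial and humoral immunity genes 8 were higher and 8 lower (adjusted p = 0.653, median -0.04, or 0.392 with library totals), with Drsl5 at -8.84 ± 0.65 and BomS1 at 5.71 ± 1.18. Without replicate 3 titled mitf BomS1 stood at 7.36 (4.89 without replicate 1 or 2), and without replicate 2 titled LacZ Drsl5 stood at -9.50. Of 88 ribosomal protein genes 31 were higher and 1, RpS14b (-0.36 ± 0.10), was lower. Library totals turned RpS14b to 0.07, made 81 ribosomal genes higher and called that list (adjusted p = 0.000703), as did leaving out replicate 2 titled LacZ (adjusted p = 0.0190). As deposited, adjusted p was 0.193, and 0.898 with an estimated correlation. Trimmed mean scaling left 11 ribosomal genes higher and 5 lower. Oxidative phosphorylation genes numbered 29 higher and 16 lower of 73 (adjusted p = 0.601, or 45 and 3 with library totals), glycolysis and sugar storage genes 6 and 12 of 21 (adjusted p = 0.0946), lipid storage and synthesis genes 14 and 5 of 21 (adjusted p = 0.193), heat shock and stress genes 11 and 7 of 24 (adjusted p = 0.992), and cell death genes 4 and 8 of 15 (adjusted p = 0.601, median -0.54, mean 0.10, or 6 and 4 with a median of -0.109 with library totals). The fatty acid synthase FASN2 differed by 6.99 ± 0.67 (7.72 and 6.06 without replicate 2 or 3 titled mitf), the lipid droplet protein Lsd-1 by -3.51 ± 0.19 and Pepck1, an enzyme of sugar synthesis, by -6.56 ± 0.76 (-7.16 and -5.58 without replicate 1 or 2 titled LacZ). Higher and lower marker genes numbered 2 and 3 of 10 for hemocytes, 5 and 0 of 13 for muscle, 3 and 1 of 10 for epidermis and discs, 0 and 5 of 7 for testis and gonad (1 and 2 with library totals), and 3 and 1 of 7 for neurons, with adjusted p from 0.19 to 0.84 for these and the gut list. The only measured ring gland gene, sad, differed by -7.06 ± 0.59, and of the salivary gland and the male lists 0 of 10 and 0 of 10 genes were matched among the tested genes. Adjusted over the list alone, the counts changed to 7 and 8 for antimicrobial genes, 23 and 1 for ribosomal genes, 11 and 9 for heat shock genes and 5 and 8 for cell death genes, and were otherwise the same as over all genes.

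Single genes differed by far more. The transporter gene Mdr50 averaged 59546 ± 5256 in prepupae titled LacZ and 10.6 ± 2.59 in prepupae titled mitf (12.35 ± 0.29), and the potassium channel gene Irk3, Obsc, Cralbp and Phyhd1 were higher by 13.86 ± 1.28, 13.44 ± 0.75, 12.10 ± 0.36 and 11.69 ± 0.27. The trypsin gene deltaTry averaged 6868 ± 1464 in prepupae titled LacZ and was listed at 0 in prepupae titled mitf. Unc-115b averaged 1558 ± 246 in prepupae titled mitf and 3406 ± 8.57 in larvae and was listed at 0 in prepupae titled LacZ. Ser7, sona and the gap junction gene Inx7 differed by -10.26 ± 0.41, -8.76 ± 0.61 and -8.49 ± 0.47. Without replicate 1 titled mitf Obsc stood at 14.31. In all 3 comparisons, where a group mean lay near 0, the size of a difference depended on the pseudocount, as for Cralbp (14.62 at 0.1 and 10.01 at 5), while the direction stayed. In all, 7366 of 10139 genes were called, 4166 higher and 3200 lower in prepupae titled LacZ, and 5612 of them by a log2 difference of at least 1. With library totals the split was 4950 to 2335. The 3 libraries of one group all lay above the 3 of the other for 76.1% of genes, against 10% by chance. The median of all genes was 0.22 as deposited, and moved by 0.41 with library totals and by -0.14 with trimmed mean scaling.

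**Figure D3:**
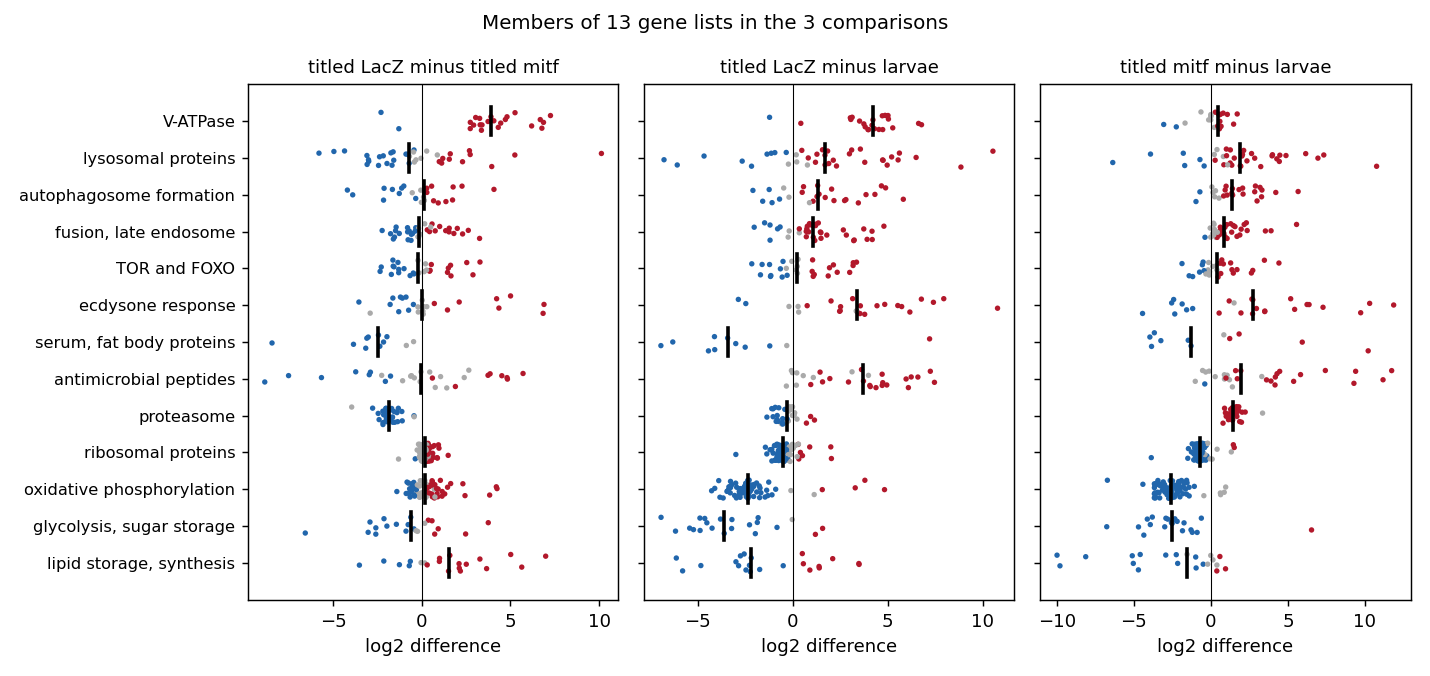
Log2 differences of the measured members of 13 gene lists in the 3 comparisons, as 1 point per gene (red called higher, blue called lower, grey not called) with a black bar at each list's median. V-ATPase genes sit at a median of 3.91 between the prepupa groups and of 4.22 and 0.45 against the larvae, and proteasome genes at -1.87, -0.32 and 1.41, where the -0.32 turns to 0.174 with library totals. In the first panel the medians of autophagosome formation, fusion, TOR and FOXO, ecdysone response and antimicrobial genes change sign with the scaling.

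The comparison of prepupae titled LacZ with larvae is, by title, the stage change with the control transgene, but Mitf itself rose in it from 391 ± 17.1 to 49795 ± 17050 (log2 difference 6.93 ± 0.20, adjusted p = 1.25e-09). It can therefore not be read as a control stage change. V-ATPase genes rose for 22 of 23 subunits (median log2 difference 4.22, adjusted p = 8.4e-07, and 0.222 as adjusted p with an estimated correlation), and Vha100-2 rose from 1151 ± 159 to 18017 ± 3548 (3.96 ± 0.15). VhaM9.7-c stood at -1.22 ± 0.15 (-0.73 with library totals). Of the 16 measured tubule markers 10 rose, 1 fell and 5 were not called (median log2 difference 1.67). The risers included SecCl, Best1, ClC-a and NKAIN at 9.74 ± 0.91, 4.58 ± 0.16, 3.12 ± 0.11 and 2.34 ± 0.12, and Alp4 fell (-0.98 ± 0.26). Those not called, CapaR, Lkr, ct, ZnT35C and Oatp58Dc, averaged only 3.37 to 37.5 in prepupae titled LacZ. Of 17 gut markers 10 rose and 3 fell. Among all 10139 tested genes, 4699 rose and 3260 fell. The autophagy genes Atg8a, Atg7, Atg18b and Atg1 rose by 3.86 ± 0.22, 4.89 ± 0.14, 5.82 ± 0.19 and 3.45 ± 0.24. CtsL1 rose from 531 ± 148 to 239490 ± 11500 (8.85 ± 0.18). Genes of oxidative phosphorylation fell for 67 of 73 members (median -2.36, adjusted p = 9.11e-19, and adjusted p = 0.344 with an estimated correlation), and genes of glycolysis and sugar storage for 18 of 21 (median -3.60, adjusted p = 1.75e-07, and adjusted p = 0.222 with an estimated correlation). Pgi, which acts after hexokinase in glycolysis, stood at -6.93 ± 0.15, and the fatty acid synthase FASN1 fell from 534910 ± 29150 to 8194 ± 3373.

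Of 25 genes of autophagosome formation 17 rose and 5 fell, the latter Atg3, Atg5, Atg10, Atg13 and Rubicon (adjusted p = 0.0448, and adjusted p = 0.416 with an estimated correlation). That call was lost without larval replicate 3 (0.0657) or replicate 1 (0.0508), 2 (0.0523) or 3 (0.0505) titled mitf, which enter through the shared fit. ref(2)P stood at 0.88 ± 0.50 (adjusted p = 0.129), and was called at 1.60 without replicate 2 titled LacZ and at 1.37 with library totals. Of 35 fusion and late endosome genes 26 rose and 6 fell (adjusted p = 0.0164, and adjusted p = 0.344 with an estimated correlation), with Syx13 at 4.80 ± 0.13, Syx17 at 1.09 ± 0.29 and dor at 4.18 ± 0.11. Of 37 lysosomal genes 24 rose and 9 fell (adjusted p = 0.119), with cathD at 1.89 ± 0.22, Lamp1 at 0.48 ± 0.10 (0.97 with library totals) and the acid nuclease DNaseII at -6.08 ± 0.24. TOR and FOXO genes rose for 12 and fell for 10 of 28 (adjusted p = 0.951, median 0.24), or 17 and 6 with library totals (median 0.729), with RagA-B at 3.36 ± 0.14 and Thor at 3.18 ± 0.19.

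Of 25 ecdysone response genes 19 rose and 2, ftz-f1 and Cth, fell (adjusted p = 0.00527, and adjusted p = 0.222 with an estimated correlation). Hr4 and Hr3, nuclear receptors of the prepupal ecdysone cascade, rose by 10.77 ± 0.37 and 7.95 ± 0.46, EcR by 2.02 ± 0.22, br by 2.496 ± 0.163 and Eip93F by 6.77 ± 0.49, and ftz-f1 fell by 2.47. Serum and fat body proteins fell for 9 of 11 genes and rose for 1, Fbp1 (7.20 ± 0.61, and 6.32 without larval replicate 3), with adjusted p = 0.0016, and adjusted p = 0.416 with an estimated correlation. Lsp1beta stood at -6.94 ± 0.37, Lsp1alpha at -6.31 ± 0.29 and Lsp2 at -2.998 ± 0.381. Of 29 immunity genes 20 rose and 0 fell, with Drs at 6.08 ± 0.26 (adjusted p = 0.0328, and adjusted p = 0.524 with an estimated correlation). The call was lost without larval replicate 2 (0.0608) and with library totals (0.0602). Cell death and remodelling genes rose for 12 and fell for 2 of 15, Dredd and Buffy (adjusted p = 0.0233, and adjusted p = 0.222 with an estimated correlation), and Dark, the apoptosome scaffold, rose by 6.50 ± 0.13.

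Ribosomal protein genes fell for 68 and rose for 7 of 88 (median -0.50, adjusted p = 2e-07, and adjusted p = 0.513 with an estimated correlation), but with library totals 16 rose and 18 fell around a median of -0.0103. Proteasome genes fell for 15 and rose for 3 of 32, the latter Prosbeta3, Rpn1 and Rpn7 (median -0.32, adjusted p = 0.0178, and adjusted p = 0.657 with an estimated correlation). With library totals 11 rose and 7 fell (median 0.174) and the call was lost (0.309), as it was without replicate 2 titled LacZ (0.129). Lipid genes rose for 8 and fell for 13 of 21 (adjusted p = 0.0328, and adjusted p = 0.416 with an estimated correlation), with Seipin, which shapes lipid droplets, at 3.49 ± 0.19. Heat shock and stress genes rose for 15 and fell for 5 of 24 (adjusted p = 0.208), among them Hsp23, a small heat shock protein, from 12.6 ± 3.39 to 29917 ± 8256. Markers that rose and fell numbered 6 and 3 of 10 for hemocytes, 1 and 7 of 13 for muscle, 10 and 3 of 17 for gut, 4 and 3 of 10 for epidermis and discs, 3 and 0 of 7 for testis and gonad (6 and 0 with library totals), and 5 and 0 of 7 for neurons, with adjusted p from 0.0828 to 0.893. Muscle markers were called as lower without larval replicate 1 (adjusted p = 0.0427) and with library totals (adjusted p = 0.0400). As deposited and with an estimated correlation, their adjusted p was 0.524. The ring gland gene sad was not called (1.13 ± 0.59, adjusted p = 0.105), except at 1.69 without replicate 2 titled LacZ and at 3.01 with a pseudocount of 0.1. Adjusted over the list alone, each count was the same as over all genes.

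Among single genes, GstD7, the acyl-CoA binding Acbp2, Aldh, Adh and the reductase Akr1B fell in prepupae titled LacZ, with log2 differences of -9.27 ± 0.68, -8.84 ± 0.29, -8.125 ± 0.186, -7.68 ± 0.15 and -7.66 ± 0.22. Cralbp, Obsc and Irk3 rose by 12.14 ± 0.36, 11.62 ± 0.75 and 11.47 ± 1.28, and brv3 and FipoQ, listed at 0 in the larvae, averaged 6447 ± 533 and 6103 ± 1454. Leaving out 1 larval library moved Irk3 to between 10.49 and 13.38 and, without replicate 1, Obsc to 10.96, and leaving out replicate 2 or 3 titled LacZ moved GstD7 to -8.31 or -10.03. With pseudocounts of 0.1 and 5 Cralbp stood at 14.69 and 10.03. In all, 7959 genes were called, 4699 that rose and 3260 that fell, of which 6483 changed by a log2 difference of at least 1. With library totals the split was 5512 to 2469. The median of all genes was 0.50, and moved by 0.45 with library totals and by -0.15 with trimmed mean scaling. Groups did not overlap for 79.9% of genes, against 10% by chance.

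The comparison of prepupae titled mitf with larvae gives the stage change for the prepupae whose Mitf stayed at the larval level. Genes of autophagosome formation rose for 18 and fell for 2 of 25, Tango5 and Atg10 (median 1.40, adjusted p = 5.66e-05, and adjusted p = 0.115 with an estimated correlation). Atg8a rose from 1102 ± 249 to 10658 ± 922 (3.29 ± 0.22), Atg1 by 3.32 ± 0.24, Rubicon by 3.19 ± 0.13 and ref(2)P from 1149 ± 165 to 9261 ± 2007 (3.00 ± 0.50). Lysosomal genes rose for 27 and fell for 6 of 37 (median 1.91, adjusted p = 0.000209, and adjusted p = 0.115 with an estimated correlation), with cathD from 3317 ± 932 to 94791 ± 1761 (4.88 ± 0.22), CtsL1 at 6.16 ± 0.18, LManI at 10.76 ± 0.38, LManII at 7.33 ± 0.17 and Lamp1 at 1.36 ± 0.10. V-ATPase genes rose for 13 and fell for 2 of 23, Vha100-2 at -2.24 ± 0.15 and Vha36-3 at -3.055 ± 0.529 (-1.78 with a pseudocount of 5), and the list was not called (median 0.45, adjusted p = 0.143). Of 16 tubule markers 6 rose and 2 fell. Proteasome genes rose for 31 and fell for 0 of 32 (median 1.41, adjusted p = 6.75e-09, and adjusted p = 0.444 with an estimated correlation), with Rpn6 at 2.23 ± 0.13. The call of Atg10 (-0.71 ± 0.27) was lost without replicate 1 titled LacZ or any 1 replicate of the larvae or of the prepupae titled mitf (-0.77 to -0.59), with library totals (-0.65) and with a pseudocount of 0.1 (-0.72).

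Fusion and late endosome genes rose for 24 and fell for 1 of 35, car (adjusted p = 2.12e-05, and adjusted p = 0.115 with an estimated correlation), with Syx13 at 5.56 ± 0.13, the ESCRT gene Hrs at 3.91 ± 0.14 and Syx17 at 1.88 ± 0.29. The fall of car (-0.38 ± 0.12) was lost without larval replicate 1 or 2 or replicate 2 or 3 titled mitf (-0.35 to -0.32) and with library totals (-0.32). TOR and FOXO genes rose for 13 and fell for 7 of 28 (adjusted p = 0.222), with the stress protein Sesn at 4.42 ± 0.12, the insulin-like peptide Ilp6 at 3.48 ± 0.23, Thor at 2.63 ± 0.19 and the growth kinase S6k at -1.41 ± 0.13. Ecdysone response genes rose for 17 and fell for 7 of 25 (adjusted p = 0.0105, and adjusted p = 0.173 with an estimated correlation). Eip93F averaged 0.456 ± 0.79 in larvae and 1692 ± 199 in prepupae titled mitf, Hr4 rose by 11.86 ± 0.37, Hr3 by 9.72 ± 0.46 and br by 2.96 ± 0.16, while EcR stood at -2.34 ± 0.22 and ftz-f1 at -2.54 ± 0.23. Immunity genes rose for 17 and fell for 1 of 29, PGRP-SA (adjusted p = 0.00351, and adjusted p = 0.444 with an estimated correlation), with Drs from 11.2 ± 3.41 to 40410 ± 1367. DptA averaged 10780 with an SD of 12300, and PGRP-SA (-0.39 ± 0.15) lost its call without larval replicate 1 or 2, replicate 1 or 2 titled mitf or replicate 1 titled LacZ (-0.42 to -0.30), and with library totals (-0.33).

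Oxidative phosphorylation genes fell for 68 of 73 (adjusted p = 3.67e-22, and adjusted p = 0.179 with an estimated correlation), glycolysis and sugar storage genes for 20 of 21 (adjusted p = 2.74e-08, and adjusted p = 0.115 with an estimated correlation) and ribosomal protein genes for 79 of 88 (adjusted p = 5.19e-11, and adjusted p = 0.444 with an estimated correlation). The only riser among the glycolysis genes was Pepck1 (6.53 ± 0.76), and the risers among ribosomal genes were RpS19b and RpS5b. Lipid genes fell for 13 and rose for 3 of 21, Lsd-1, Hsl and Fatp1 (adjusted p = 0.000906, and adjusted p = 0.173 with an estimated correlation). FASN1 fell from 534910 ± 29150 to 606 ± 40.4, and FASN2 stood at -9.98 ± 0.67 (-10.71 and -9.05 without replicate 2 or 3 titled mitf). Cell death and remodelling genes rose for 9 and fell for 2 of 15, hid and Damm (adjusted p = 0.0105, and adjusted p = 0.115 with an estimated correlation), with the matrix protease Mmp2 at 9.43 ± 0.39. Serum and fat body proteins rose for 4 of 11, Fbp1, Fbp2, Obp99b and Tsf1, and fell for 6 (median -1.28, mean 0.24, adjusted p = 0.52). Fbp1 rose by 10.21 ± 0.61 (9.33 without larval replicate 3), and Lsp2 stood at 0.85 ± 0.38 (adjusted p = 0.076), and was called at 1.09 without larval replicate 1, at 0.90 with library totals and at 0.84 with the filter at 10 CPM. Heat shock and stress genes rose for 9 and fell for 8 of 24 (adjusted p = 0.434), Hsp23 reaching 234120 ± 8975. Muscle markers fell for 10 and rose for 1, sls, of 13 (adjusted p = 0.0149, and adjusted p = 0.444 with an estimated correlation), and testis and gonad markers rose for 6 of 7 (adjusted p = 0.0105, and adjusted p = 0.163 with an estimated correlation), Mst87F from 0 in the larvae to 360 ± 17.4. Rises and falls numbered 3 and 1 of 10 for hemocytes, 4 and 6 of 17 for gut (median -0.997, mean 0.344), 1 and 3 of 10 for epidermis and discs and 2 and 0 of 7 for neurons, with adjusted p from 0.222 to 0.658, and sad rose by 8.19 ± 0.59. Adjusted over the list alone, rises and falls became 18 and 7 for ecdysone genes, 16 and 1 for immunity genes, 3 and 81 for ribosomal genes, 1 and 11 for muscle and 7 and 0 for testis, and were otherwise the same as over all genes.

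Among single genes, Ama and Sp212 rose by 13.96 ± 0.41 and 12.14 ± 0.36 in prepupae titled mitf, and santa-maria, listed at 0 in the larvae, averaged 50390 ± 1635. Aldh, GstD7 and ssp7 fell, with log2 differences of -9.80 ± 0.19, -10.35 ± 0.68 and -9.30 ± 0.13. Ama stood at 13.36 without larval replicate 1, and at 15.36 and 12.44 with pseudocounts of 0.1 and 5. In all, 6737 genes were called, 3524 that rose and 3213 that fell, and 4916 of them by a log2 difference of at least 1. The median of all genes was 0.08, and groups did not overlap for 71.1% of genes, against 10% by chance.

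**Figure D4:**
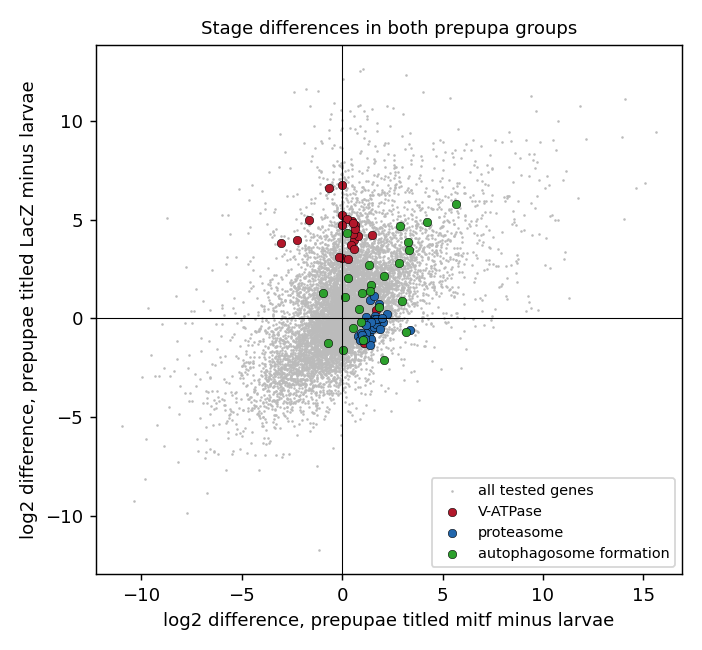
Log2 difference from larvae of each of the 10139 tested genes in prepupae titled mitf (horizontal) and in prepupae titled LacZ (vertical), 1 point per gene, with 3 gene lists in colour. V-ATPase genes sit near a median of 0.45 on the horizontal axis and 4.22 on the vertical axis, and proteasome genes near 1.41 and -0.32, the latter 0.174 with library totals.

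The stage changes of both prepupa groups shared 4450 calls in the same direction. From the larvae, 2397 genes rose in both groups and 2053 fell in both, where independent lists of these sizes would share 1633 and 1033. Atg8a, Atg1, Hr4 and CtsL1 rose in both, and Lsp1alpha, Lsp1beta, FASN1 and ftz-f1 fell in both. The 3 larval libraries serve both comparisons, which alone gave 66.47% of simulated unchanged genes the same sign, and 68.67% was observed. In the data 7959 and 6737 of 10139 genes were called, so chance spread in the larvae sets few of their signs. The simulated share therefore does not tell how much of the observed one comes from the shared larvae. The 20 simulations gave a mean of 0 shared calls. No gene was changed in them, so hardly any call could arise, and this says nothing about the overlap of called genes. With 3 libraries the larvae could not be split between the comparisons, so part of the excess over independent lists may come from the shared libraries. Genes that rose in prepupae titled mitf were lower in prepupae titled LacZ in 1671 cases, and higher in 979. Genes that fell in prepupae titled mitf were higher in prepupae titled LacZ in 1648 cases, and lower in 810. These overlaps share the libraries titled mitf, which enter both comparisons with opposite signs, so they are given as counts alone. Simulations without any change gave a mean of 0.05 genes called in both, and at most 1, which for the same reason says nothing about these counts.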

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

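The tests in this part of an earlier stage, of library scaling and of other splits were planned before their results were seen. The counts and the share below with trimmed mean scaling were added after the data had been examined.

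Stage changes that ran in opposite directions in the prepupa groups were singled out. The prepupa groups also differed from each other in a test of that difference for each gene. Opposite calls against the same larvae in the same fit entail this, so the test removed no gene and adds no support. There were 498 genes that rose from larvae to prepupae titled mitf and fell from larvae to prepupae titled LacZ, among them Tsf1, Nt5a and laza. Library totals gave 306 such genes, 291 of them the same, and trimmed mean scaling gave 556, with 483 the same. There were 691 genes that fell in prepupae titled mitf and rose in prepupae titled LacZ, among them Phyhd1, Zmynd10, tty, bnl and CAH9. Library totals gave 796 of these, 634 of them the same, and trimmed mean scaling gave 642, with 632 the same. As deposited, independent lists would have shared 1133 and 1489 genes, so the 498 and 691 were fewer than that. The shared larval libraries favour the same direction, so part of this shortfall may come from them. Of the proteasome subunits 15 rose in prepupae titled mitf and fell in prepupae titled LacZ, which became 7 with library totals and 17 with trimmed mean scaling.

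The prepupa groups differed in most genes, and 3 explanations were weighed. Had the prepupae titled LacZ merely been at an earlier stage, with genes changing steadily, their means should lie between those of larvae and prepupae titled mitf. This held for 23.2% of the called genes, while 3407 lay above both and 2254 below both. Genes that rise and fall within the interval can also lie outside it. The values therefore argue only against an earlier stage with steady change, and a later stage was not examined. Library scaling as the whole cause was argued against, since 88.2% of the calls kept their direction with library totals, which raise titled LacZ, and 96.1% with trimmed mean scaling, which lowers it. The biological explanation that the design gives, Mitf overexpression in 1 of the groups, stays open and was not tested apart from any other difference between the groups, since each group has a single genotype.

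Other splits of the 6 libraries of a comparison into 3 and 3 were counted. Between the prepupa groups 1 of 10 splits, the real one, called as many as 7366 genes, and the highest other called 1. Between prepupae titled LacZ and larvae it was 1 of 10, with 7959 genes and 0 in the highest other, and between prepupae titled mitf and larvae 1 of 10, with 6737 and 2. With 10 splits no share under 0.1 can arise. Every other split mixes the compared groups, so their difference enters the spread and hardly any gene can be called. The low counts of the other splits therefore add no support.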

How the results depend on the processing

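The trimmed mean scaling and the list tests with library totals were chosen after the data had been examined. Named here as not run, because they need whole counts, are a DESeq2 Wald test, limma voom, an edgeR fit with either scaling and its count filter, and the lists under DESeq2 size factors, the last being the scaling the values already carry. The Mitf difference between the prepupa groups stayed between 6.74 and 7.43 in every setting run. Leaving out each library gave 6609 to 7411 genes between the prepupa groups, 7342 to 7915 between prepupae titled LacZ and larvae, 6363 to 6938 between prepupae titled mitf and larvae, 4185 to 4476 changed the same way in both groups and 3 to 4 lists between the prepupa groups. A filter at 10 CPM left 5538 genes to test, and called 4693 between the prepupa groups (4665 of them also called the same way without it) and 4853 between prepupae titled LacZ and larvae (4842), fewer since fewer genes were tested. The 3319 genes that changed from larvae to prepupae titled mitf and differed the opposite way between prepupae titled LacZ and titled mitf became 2011 with a minimum log2 change of 1, which is stricter by construction. With the correlation within lists estimated, 0, 0 and 0 lists were called in the 3 comparisons, against 3, 12 and 13 with the preset value, so those list calls depend on that choice. With fry, which does not set a list against other genes, 14 lists were called between the prepupa groups, 19 between prepupae titled LacZ and larvae and 17 between prepupae titled mitf and larvae. With library totals 5 lists were called between the prepupa groups, and RpS14b reversed from -0.36 to 0.0699, a move in the direction and of the size of the shift of all genes by 0.41. Depth limits the genes near 1 read, which was worth 0.746 to 1.38 of the deposited unit. With 3 libraries a group, recovery of 2-fold changes was 46% to 60% on simulated data. Few genes were changed in that simulation, which made the adjusted threshold stricter than in the data. Recovery in these comparisons may therefore be higher.

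With replicate number as a block, 7300, 7907 and 6662 genes were called in the 3 comparisons, of which 7212, 7840 and 6580 were also called the same way without it. It gave 4412 genes changed the same way in both groups, 3245 opposed ones, 3, 12 and 13 lists and a Mitf difference of 6.998. Libraries with the same number correlated at -0.087 to 0.122 in their deviations from the group means, and 5 of 9 correlated best with their own number, so the numbers were not taken to pair the libraries. Of the named genes, PGRP-SA and VhaAC39-2 lost their calls against larvae in prepupae titled mitf.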

Other observations

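Of the tests in this part, those of exchanged titles, of midgut tissue and of library scaling were written after the values had been seen.

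Several genes were near silent in 6 libraries and abundant in the 3 titled LacZ. Cln3, brv3 and FipoQ averaged 0.434, 1.32 and 1.01 in prepupae titled mitf and were listed at 0 in the larvae, against 1480, 6447 and 6103 in prepupae titled LacZ. Unc-115b did the reverse, and was listed at 0 in the prepupae titled LacZ against 3406 in the larvae. The genes santa-maria and Ama, near silent in larvae, averaged 50390 and 36068 in prepupae titled mitf and 720 and 1352 in prepupae titled LacZ.

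Within the prepupae titled LacZ, replicate 2 had the highest Mitf, 68535, and the lowest ref(2)P, 773. Matching by symbol or synonym among the tested genes found no salivary gland glue gene and no listed gene of the Y chromosome or of male dosage compensation. It also did not find Tor, Vha44 and fab1. Since 53 identifiers had no symbol, this does not show that these genes were absent from the files.

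Mitf was far higher in the libraries titled LacZ than in those titled mitf. The lowest library titled LacZ lay 85.7 times above the highest other, and those titled mitf stood at 0.958 of the larval mean. Exchanged titles would give such values, but that explanation was drawn from them, so they do not test it. Of the other labels, the table names are opposite to the titles, while the genotype label gives the Mitf transgene to all 6 prepupa samples. The Mitf values argue against overexpression in the libraries titled mitf, and so against the title and the genotype label of those libraries. They go with the table names. How the labels came to conflict stays open. If the titles were exchanged, each printed difference of titled LacZ minus titled mitf is Mitf overexpression minus control.

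V-ATPase subunits were higher in the prepupae titled LacZ, by a median log2 difference of 3.91. Library scaling was argued against as the cause, since a factor per library moves all genes alike and the subunits' median lay 3.69 above that of all genes (quartiles 2.94 and 4.82). Trimmed mean scaling, which lowers the difference, left it at 3.76. For the marker counts that follow, 4166 of all 10139 tested genes were called higher in prepupae titled LacZ. Midgut tissue stays open, since 10 of 17 gut markers were higher (median log2 difference 1.76) and deltaTry averaged 6868 against 0 in prepupae titled mitf, although 4 were lower and the 5 most abundant had a median level of 0.00974 of that of the subunits. Malpighian tubule tissue, which is rich in this pump, stays open too, since 10 of 16 tubule markers were higher with a median log2 difference of 1.21 (quartiles 0.701 and 3.13), although their median level was 253.2 against 11580 for the subunits. An action of Mitf on these genes in the fat body was not tested, and the pattern can not be called biological from these data.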
